A study of Arabidopsis thaliana with 17 samples.

How the data were processed

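Whole seedlings of Arabidopsis thaliana, accession Col-0, and of an hsfa2 knockout line in the same background were profiled on Affymetrix arrays with 22810 probe sets. HSFA2 encodes a heat shock transcription factor. Per the labels' protocols, the plants were kept under 16 h days at 22 °C and collected at 7 d of age. Naive seedlings were never heated. Primed seedlings spent 1 h at 37 °C at 4 d of age and then recovered for 3 d. Triggered seedlings were heated for 1 h just before collection, and primed and triggered seedlings received both treatments. The wild type contributed 11 arrays (3 naive, 2 primed, 3 triggered, 3 primed and triggered) and hsfa2 6 arrays (2 each for naive, triggered, and primed and triggered). The labels call the arrays of a group biological replicates. No array of hsfa2 seedlings that were only primed was among those analysed, so the primed level in hsfa2 is not known here.

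The deposited table holds intensity values on a linear scale, from 3.94 to 19602 with 0 zeros, which the authors made with RMA (background correction, normalization across arrays and a robust summary of the probes of each probe set), per the submitters' processing notes. The version of RMA and other settings are not given in the sources used here. RMA normally gives log2 values, so the deposited intensities were put back on the log2 scale, without a pseudocount. After removal of 64 Affymetrix control probe sets, 22746 probe sets were tested. Because the arrays had been normalized together by the authors, no further normalization was applied in the analysis reported first. That step normally makes most of the distribution alike across arrays, so a change in the total RNA per seedling would not be seen. Array medians still differed, as given with the results.

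Probe sets were named through the platform's annotation and updated by gene identifier with a RefSeq table of assembly TAIR10.1. In that annotation 13513 probe sets had 1 gene, 503 had several and 8730 were not listed. Of those with 1 gene, 13436 matched a gene of the RefSeq table and 1580 had a symbol other than the locus. Probe sets that are not listed are given by their identifier and count as unnamed, not as lacking a gene. The array values carry no genome build, so no coordinates are given. HSFA2 itself had no listed probe set, so the genotype labels were not checked on the targeted gene.

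Group means were fitted with limma 3.58.1 in R 4.3.3 (statmod 1.5.0) to the 17 arrays and 7 groups together, which left 10 residual degrees of freedom and a prior of 2.92. In all, 12 contrasts were tested with moderated statistics and Benjamini-Hochberg adjustment over all probe sets. A probe set was called at an adjusted p under 0.05, and all adjusted p-values below come from limma. Counts at an unadjusted p under 0.05 are given for scale, as a share of 0.05 of all probe sets would reach it without any difference. Log2 changes are given with the standard error of the fit (SE), levels as the mean log2 intensity with the SD between arrays. The 12 contrasts covered priming, triggering, and priming before triggering in the wild type, the interaction of both treatments, the mean heat response, the genotype differences in each condition, the same responses in hsfa2, and the differences in response between the genotypes. The mean heat response (triggered and primed and triggered, against naive) is orthogonal to the memory contrast, although both use the same heated arrays and a rise with priming also raises the mean, and served to class probe sets as heat-induced or heat-repressed at a change of at least 2-fold.

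Before the data were examined, 22 gene lists with 380 entries were fixed, of which 72 entries had a probe set with 1 gene. The lists were heat shock factors, small heat shock proteins, HSP70, HSP90, HSP100 and partners, endoplasmic reticulum folding, heat memory genes known from earlier work, antioxidant and redox signalling, raffinose and inositol synthesis, photosynthesis, expansins and xyloglucan enzymes, cell cycle and DNA replication, ribosome biogenesis, the circadian clock, auxin response and the PIF pathway, abscisic acid and dehydration response, defence and jasmonate response, hypoxia response, flavonoid and anthocyanin synthesis, glucosinolate synthesis, root and root hair markers, guard cell markers, seed storage markers and reference genes. The 11 lists with at least 3 measured members were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry, adjusted over lists within a contrast. The other 11 lists were not tested as sets. A gene with several probe sets was represented by the one with the highest mean. Lists of mitochondrion-encoded and plastid-encoded genes were added after the values had been seen.

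Named genes follow a rule fixed before the data were examined. It takes HSFA2, the measured heat memory genes of earlier work, the 10 largest rises and the 10 largest falls per contrast among called probe sets with a symbol other than the locus whose arrays did not overlap between the groups (for interactions, called probe sets only), and up to 4 called members of each list, or up to 2 with the smallest p where none was called. Loci and probe sets outside this rule were chosen after their values had been seen, which the text says where it applies.

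Replicates were compared before averaging. Correlations within a group ran from 0.963 to 0.997, and 0 pairs of arrays were identical. The replicate numbers in the labels were checked for pairing through the correlation of the deviations from the group means. Between triggered and primed and triggered wild-type arrays it was 0.56, 0.64 and 0.66 for the numbers 1 to 3, all above the limit of 0.1, so these numbers pair the samples. The pairing comes from the data, as the labels do not say what a number stands for. The other groups did not meet that limit or had fewer than 3 pairs.

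Alternatives fixed beforehand were a filter on dim probe sets (mean above the 40th percentile), quantile normalization, centring of each array on its median, a variance trend with robust moderation, array weights, the replicate number as a block, removal of probe sets shared by several transcripts, a fit of only the groups compared, a 2-fold minimum, and leaving out each array in turn. The spike-in controls showed a batch of 3 arrays, described with the results, and settings for this batch and a paired fit of 6 arrays were chosen after seeing the data. No sequencing depth applies to arrays, and the number of arrays per group limits the precision. In a test on simulated data, 100 of the 22746 probe sets were changed by 1 log2 unit and another 100 by 2 log2 units at the same time. For priming before triggering in the wild type, the fit recovered 72 of 100 changes of 1 log2 unit and 96 of 100 changes of 2 log2 units. The same numbers were 57 and 91 for priming before triggering in hsfa2, and 27 and 82 for the difference in that response between the genotypes. Calls among unchanged probe sets numbered 11, 6 and 4 in these 3 comparisons. The simulated arrays had the same spread in every group, no pairing and no heat response, unlike the real ones. The numbers recovered are therefore a rough guide to what the real arrays could show. Figures were drawn with matplotlib 3.10.9.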

Results

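Transcript levels were measured in 17 arrays of whole Arabidopsis seedlings that were never heated (naive), heated 3 d before collection (primed), heated just before collection (triggered) or heated at both times. In the wild type there were 3 naive, 2 primed, 3 triggered and 3 primed and triggered arrays, and in the hsfa2 knockout 2 naive, 2 triggered and 2 primed and triggered arrays. Median intensities lay between 51.8 and 58.9 in the arrays heated just before collection and between 60.1 and 64.2 in the naive and primed arrays. A first principal component that held 56.8% of the variance was followed by one with 12.3%. In 3 arrays (wild-type naive replicate 3 and both primed replicates) the bacterial hybridization control bioB was at a log2 intensity of 4.42 ± 0.02 (SD), against 7.65 ± 0.38 in the other 14. The same 3 arrays had poly-A spike controls at 9.66 ± 0.26, against 6.72 ± 0.73 in the others, and a larger difference between the 3′ and the 5′ probe sets of GAPDH, 2.11 ± 0.23 against 0.96 ± 0.36. By the poly-A spikes, however, wild-type naive replicate 2 (8.83) lay nearer to these 3 arrays (9.39 to 9.90) than to the remaining ones (5.99 to 7.47). Wild-type naive replicate 1 had a 25S rRNA signal of 8.57, against 11.39 to 12.80 in all other arrays. All primed arrays therefore share the batch of low bioB signal with a single naive array. HSFA2 had no listed probe set, so the knockout was not checked on its target.

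The heat response of seedlings without earlier heat was read from the triggered and the naive wild-type arrays. Heat shock and mitochondrial transcripts were among the largest rises of named genes. The small heat shock protein gene ATHSP22.0 rose by 9.11 log2 units (SE 0.47), from a level of 4.00 ± 0.06 to 13.12 ± 0.10 (SD, n = 3 and 3). Hop3, a co-chaperone that links HSP70 and HSP90, rose by 7.37 (SE 0.41), Fes1A, a partner of cytosolic HSP70, by 6.42 (SE 0.20), and HSA32, a heat acclimation protein, by 5.16 (SE 0.44). Signals for transcripts of the mitochondrial genome for subunits of the respiratory chain rose as well: nad6 by 6.86, nad5 by 5.24, nad4L by 4.99, nad9 by 4.95 and cox2 by 4.79, and the cytochrome c biogenesis gene ccb452 rose by 4.55. A change in polyadenylation and transcription of the nuclear copy of mitochondrial DNA were not tested as sources of these signals.

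Among the gene lists, 8 of 10 measured small heat shock protein genes rose after triggering, over all probe sets and adjusted over the list alone, with a list median of 8.01 log2 units (camera adjusted p = 3.06e-14, and adjusted p = 0.0380 with an estimated correlation). Among them were AT1G53540 (9.88, SE 0.84), AT1G52560 (9.40, SE 0.35), ATHSP22.0 and AT5G51440 (8.43, SE 0.37), whose naive levels (3.57 to 4.38) lay near the lowest and whose triggered levels (12.82 to 13.78) near the highest intensities, so the order of these changes carries little information and larger ones may be missed. The remaining 2 members, AT4G21870 at −0.75 (SE 0.27) and AT5G47600 at 0.45 (SE 0.37), did not pass over all probe sets, while AT4G21870 was lower adjusted over the list alone. Of 9 genes of the HSP70, HSP90, HSP100 and partners list, 8 rose, also adjusted over the list alone, with a median of 3.71 (camera adjusted p = 3.78e-16, and adjusted p = 0.00486 with an estimated correlation). Besides Hop3, Fes1A and HSA32, AT5G48570 rose by 7.08 (SE 0.44). The 3 measured heat memory genes of earlier work (ATHSP22.0, HSA32 and AT5G48570), which are also members of these lists, all rose, with a median of 7.08 (camera adjusted p = 1.14e-07, and adjusted p = 0.0380 with an estimated correlation).

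Some genes for cell wall extension and the measured root markers were lower after triggering. Of 11 expansin and xyloglucan enzyme genes, 4 fell over all probe sets and 7 adjusted over the list alone, with XTH19 at −2.85 (SE 0.50), EXPA4 at −1.56 (SE 0.26), EXGT-A3 at −1.50 (SE 0.28) and EXPA8 at −1.38 (SE 0.37). The list median was −0.92 (camera adjusted p = 0.000231), a call that was lost with an adjusted p = 0.0620 under an estimated correlation. All 3 measured root and root hair markers fell, also adjusted over the list alone: the beta-glucosidase gene PYK10 by 1.84 (SE 0.21) on the log2 scale, EXPA7 to −1.30 (SE 0.24) and EXPA18 to −1.20 (SE 0.19). Their median was −1.30 (camera adjusted p = 0.000310, and adjusted p = 0.0380 with an estimated correlation). In the photosynthesis list 1 of 7 genes, the phosphoribulokinase gene PRK, fell over all probe sets (−0.74, SE 0.11) and 6 adjusted over the list alone. Its median of −0.27 passed camera (adjusted p = 0.00364) but not with an estimated correlation (adjusted p = 0.0803), and was −0.12 with each array centred on its median. Other named genes with large falls were the beta-glucosidase BGLU33 (−3.15, SE 0.27), DRT100 (−2.79), the subtilase SBT4.12 (−2.76), the plastid ribosomal protein gene rps18 (−2.37), BRH1 (−2.27), ZW9 (−1.88), CSLC5 (−1.79) and ATSBT5.2 (−1.74). The level of rps18 varied widely between triggered arrays, 6.88 ± 1.47 (SD, n = 3).

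The other lists did not pass camera after triggering. In the antioxidant list (4 measured, camera adjusted p = 0.677) the zinc finger gene STZ rose by 2.56 (SE 0.76), although its level varied widely between naive arrays, 7.27 ± 2.30 (SD, n = 3). In the abscisic acid and dehydration list (3 measured, adjusted p = 0.0664) COR47 rose by 1.78 (SE 0.35). None of the measured genes of the cell cycle list (3, adjusted p = 0.747) or of the auxin list (4, adjusted p = 0.747) was called, the smallest p belonging to AUR2 at 0.22 (SE 0.23) and GH3.3 at 0.45 (SE 0.33). Of 3 reference genes (adjusted p = 0.815), AT2G28390 fell to −0.42 (SE 0.11).

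In total, limma called 3502 of 22746 probe sets after triggering, 1341 higher and 2161 lower, of which 1432 changed at least 2-fold (611 higher and 821 lower). Centring each array on its median moved the changes by 0.15 log2 units on average and the calls to 2831 higher and 1493 lower, so the balance of rises and falls rests on the scaling. Fitted without the other groups, the comparison gave 1832 calls.

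What a past heat treatment leaves behind was read from the primed and the naive wild-type arrays. After 3 d of recovery 1 probe set passed the threshold, that of AT4G10270, a gene of the wound-responsive family, which was chosen after its value was seen. Its level was 5.90 ± 0.43 (SD, n = 2) in primed and 4.11 ± 0.08 (SD, n = 3) in naive seedlings, a rise of 1.79 (SE 0.20, limma adjusted p = 0.0116). The small heat shock protein list had a median of 1.4003 log2 units above naive, with 0 of 10 members called by limma over all probe sets (2061 of all probe sets had an unadjusted p under 0.05) and 6 adjusted over the list alone, among them AT1G53540 at 3.42 (SE 0.93) and AT1G52560 at 1.54 (SE 0.40). This rested on 1 of the 2 primed arrays: against the naive mean the list median was 2.37 in primed replicate 2 and 0.24 in replicate 1, where the naive arrays lay between −0.24 and 0.16.

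Camera gave an adjusted p = 4.59e-08 for small heat shock proteins in primed seedlings, and an adjusted p = 0.141 with an estimated correlation. The same pair of values was 5.31e-05 and 0.141 for the HSP70, HSP90, HSP100 and partners list (median 0.41, 3 of 9 adjusted over the list alone). It was 0.00104 and 0.141 for the heat memory genes of earlier work (median 1.54, 3 of 3), 0.01004 and 0.207 for expansins and xyloglucan enzymes (median 0.42, 0 of 11) and 0.00711 and 0.141 for root markers (median 0.54, 2 of 3). Within the 3 arrays that share the low bioB signal, which hold 1 naive array, these medians were 0.94 for small heat shock proteins, 0.50 for HSP70, HSP90, HSP100 and partners, 0.87 for the memory genes, −0.12 for expansins and xyloglucan enzymes, whose direction turned, and 0.64 for root markers. The remaining 6 lists had camera adjusted p-values between 0.238 and 0.929. The memory genes of earlier work also differed between the primed arrays. HSA32 was at 5.65 in primed replicate 1 and 8.07 in replicate 2 (naive mean 5.75), ATHSP22.0 at 4.21 and 6.95 (naive mean 4.00), and AT5G48570 had an SD of 1.67 between them.

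The call of AT4G10270 ended with the batch as a block (1.71, adjusted p = 0.618), and the count of calls was 0 without naive replicate 1 or without naive replicate 2. Without naive replicate 3 it was 542, without primed replicate 1 it was 40 and without primed replicate 2 it was 66.

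**Figure D1:**
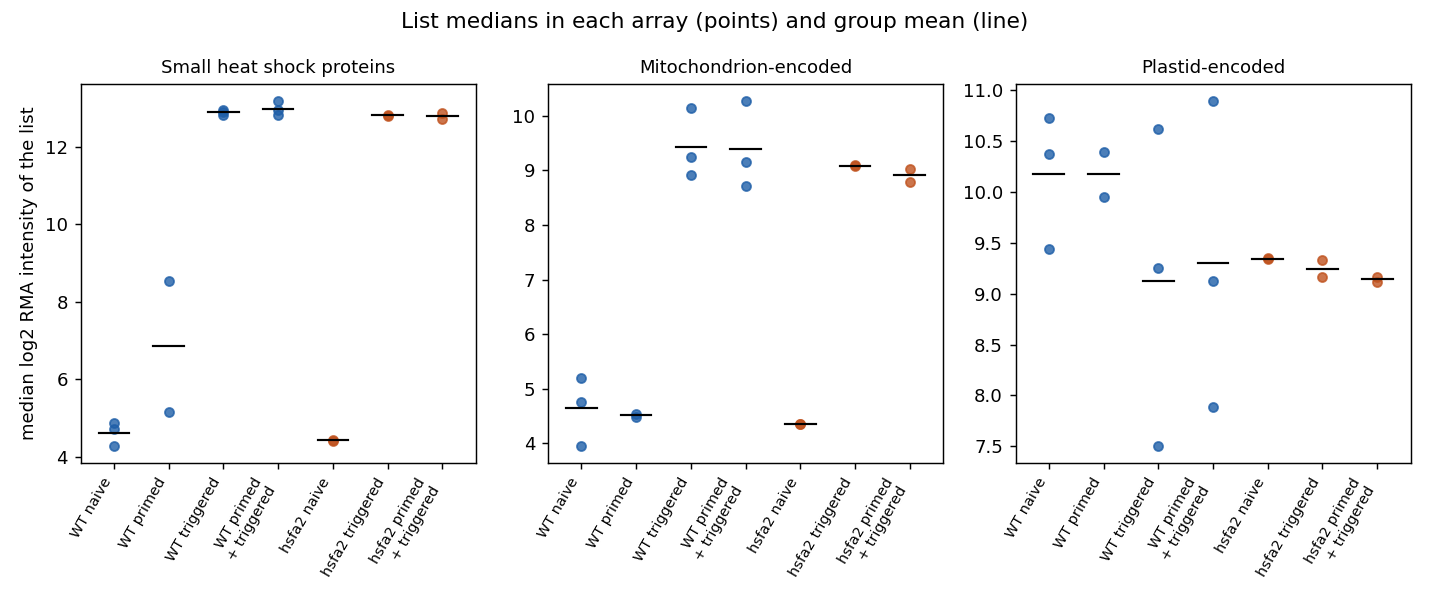
Median log2 RMA intensity of the small heat shock protein, mitochondrion-encoded and plastid-encoded gene lists (vertical axes, separate scales) in each array (points; wild type blue, hsfa2 orange) and as the group mean (line), by group. Primed replicate 2 lies at 8.54 for small heat shock proteins and primed replicate 1 at 5.16, while triggered arrays of both genotypes lie near 13; the mitochondrial medians were higher in every heated array.

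Transcriptional memory, the effect of earlier heat on the level reached after later heat, was read from primed and triggered against triggered wild-type seedlings. UGT71C2, which encodes a glycosyltransferase, was higher by 2.37 log2 units (SE 0.24, limma adjusted p = 0.000855), at 7.94 ± 0.34 after both treatments against 5.56 ± 0.31 after triggering alone (SD, n = 3 each). Triggering alone had left it near the naive level of 5.41 ± 0.37. UBA1A, which encodes an RNA-binding protein, was higher by 1.03 (SE 0.14, adjusted p = 0.00700). These 2 genes alone had a symbol among the 70 probe sets called, so further loci were chosen after their values had been seen. The seed maturation protein gene AT2G21820 was higher by 3.14 (SE 0.26), AT5G40645 by 2.04 (SE 0.17) and AT1G02700 by 1.99 (SE 0.24). The GDSL-type lipase gene AT5G55050 was higher by 1.94 (SE 0.26), AT5G07330 by 1.81 (SE 0.20) and the HSP70 family gene AT1G11660 by 1.30. Among unnamed probe sets the largest rises were those of 258603_at (3.27, SE 0.44), 245903_at (2.67, SE 0.38) and 256652_at (2.60, SE 0.17).

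The chaperone genes with the largest heat responses were not called. The change with priming was 0.29 (SE 0.47) for ATHSP22.0, 0.07 (SE 0.44) for HSA32, 0.05 (SE 0.44) for AT5G48570 and 0.00 (SE 0.84) for AT1G53540. The spread of these genes is widened by the primed arrays: paired by replicate number in the 6 arrays, 4 of the 19 genes of the 3 heat lists were higher in every pair, such as ATHSP22.0 (0.31, 0.33 and 0.23), and 2 were lower in every pair, such as Hsp70-2 (−0.69, −0.49 and −0.21). None was called (smallest limma adjusted p = 0.280), so small changes either way are not excluded. After triggering, ATHSP22.0, AT5G48570 and AT1G53540 lay between 13.04 and 13.78, near the highest log2 intensity of any array (14.26), where a further rise may not be seen. No list passed camera, with medians of 0.10 for small heat shock proteins, −0.01 for HSP70, HSP90, HSP100 and partners and 0.07 for the memory genes of earlier work, and adjusted p-values between 0.795 and 0.985 over the 11 lists. Of the 70 called probe sets 69 were higher and 1, AT5G40450, was lower (−0.72, SE 0.10), and 46 changed at least 2-fold.

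The rises were then set beside the heat response itself. The mean heat response over triggered and primed and triggered seedlings comprised 5199 calls (2035 higher and 3164 lower, or 4877 and 2196 with each array centred on its median). It included, among genes with a symbol, ATHSP22.0 (9.26), Hop3 (7.41), nad6 (6.69) and Fes1A (6.39), and BGLU33 (−3.10), SBT4.12 (−2.74), XTH19 (−2.55) and DRT100 (−2.44) among the falls. With an estimated correlation, the only list that passed camera in this mean response was HSP70, HSP90, HSP100 and partners (8 of 9 higher, median 3.68, adjusted p = 5.01e-14, and adjusted p = 0.00829 with an estimated correlation). Small heat shock proteins (8 of 10 higher, median 8.05, 8.17e-13), the earlier memory genes (3 of 3 higher, median 7.10, 8.85e-07) and root markers (3 of 3 lower, median −1.23, 0.00102) had an adjusted p = 0.0549 with an estimated correlation. Expansins and xyloglucan enzymes (5 of 11 lower, median −0.88, 0.00102) and photosynthesis genes (4 of 7 lower, 6 over the list alone, median −0.25, 0.00307) had an adjusted p = 0.0835 with an estimated correlation. The median of the former was −0.53 with the spike-in batch as a block, and that of the latter −0.10 with each array centred on its median. The other 5 lists had camera adjusted p-values between 0.106 and 0.680. Of 721 probe sets induced at least 2-fold, 47 were higher and 0 lower after priming by limma, and of 921 repressed ones 1 was higher and 1 lower. The other 21 of the 69 higher probe sets were in neither class. The mean includes the level after both treatments, so a rise with priming itself moves a probe set towards the induced class: with triggering alone 20 of the 47 stayed under a 2-fold rise, such as UGT71C2 at 0.16, and 27 of the 69 were called at least 2-fold higher. Examples in the induced class were AT5G07330, with a mean heat response of 7.86, AT5G53680 with 6.75 and AT5G05220 with 4.40.

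For most of these probe sets the primed seedlings differed little from naive ones before the later heat. In primed against naive seedlings the 69 probe sets had a median change of 0.08, with 41 of them above 0, and of 0.10 within the arrays of low bioB signal. Of the 69, 9 were above 0.5, led by 245903_at at 1.87, AT5G07330 at 0.76, AT1G58170 at 0.74 and AT1G62290 at 0.65. For AT5G40830 the difference between primed and naive seedlings (0.56) was close to that between primed and triggered and triggered ones (0.65). The overlap of the calls was 0, with 0.00303 expected for independent lists, which says little as 1 probe set was called after priming by limma (1098 probe sets reached an unadjusted p under 0.05 in the memory comparison). The 1098 are slightly fewer than the share of 0.05 of all probe sets that would be reached without any difference. For 4 probe sets limma called the response to later heat itself larger in primed than in unprimed seedlings: AT2G21820 by 2.96 (SE 0.39, adjusted p = 0.0235), 256652_at by 2.66 (SE 0.25), AT5G40645 by 2.104 (SE 0.26) and AT1G68620 by 1.46 (SE 0.18). AT5G40645 was near background (2.50 to 2.89) in all groups but the primed and triggered wild type, so its higher level there is a lower limit. Its differences between responses also subtract changes between levels near background, so their size is uncertain in both directions. In that interaction the small heat shock protein list had a median of −1.24 (camera adjusted p = 2.79e-05, and adjusted p = 0.353 with an estimated correlation). The HSP70, HSP90, HSP100 and partners list had −0.63 (6.98e-05, and adjusted p = 0.264 with an estimated correlation) and the earlier memory genes −1.28 (0.00954, and adjusted p = 0.353 with an estimated correlation), which includes the difference of primed replicate 2 described above. The other 8 lists had adjusted p-values between 0.268 and 0.866.

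The count of 70 fell to 19 without triggered replicate 1 or without primed and triggered replicate 3, to 24 without triggered replicate 2 or without primed and triggered replicate 1, and to 4 in a fit of only these 6 arrays. In those 6 arrays with the paired replicate numbers as a block, a setting chosen after seeing the data, it was 142, of which 137 were higher and 56 were among the 70. The 4 interaction calls became 1 with the spike-in batch as a block, 0 when the naive arrays with bioB signal were left out, and 1 without naive replicate 1, triggered replicate 1 or primed and triggered replicate 3. They became 2 without primed and triggered replicate 1, 10 without replicate 2 of that group, 16 without naive replicate 3, 29 without primed replicate 1 and 17 without primed replicate 2. The 47 heat-induced probe sets were 15 and 20 without triggered replicates 1 and 2, and 18 and 17 without primed and triggered replicates 1 and 3. The overlap with the primed calls was 3 without naive replicate 3 or primed replicate 1, and 1 without primed replicate 2.

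**Figure D2:**
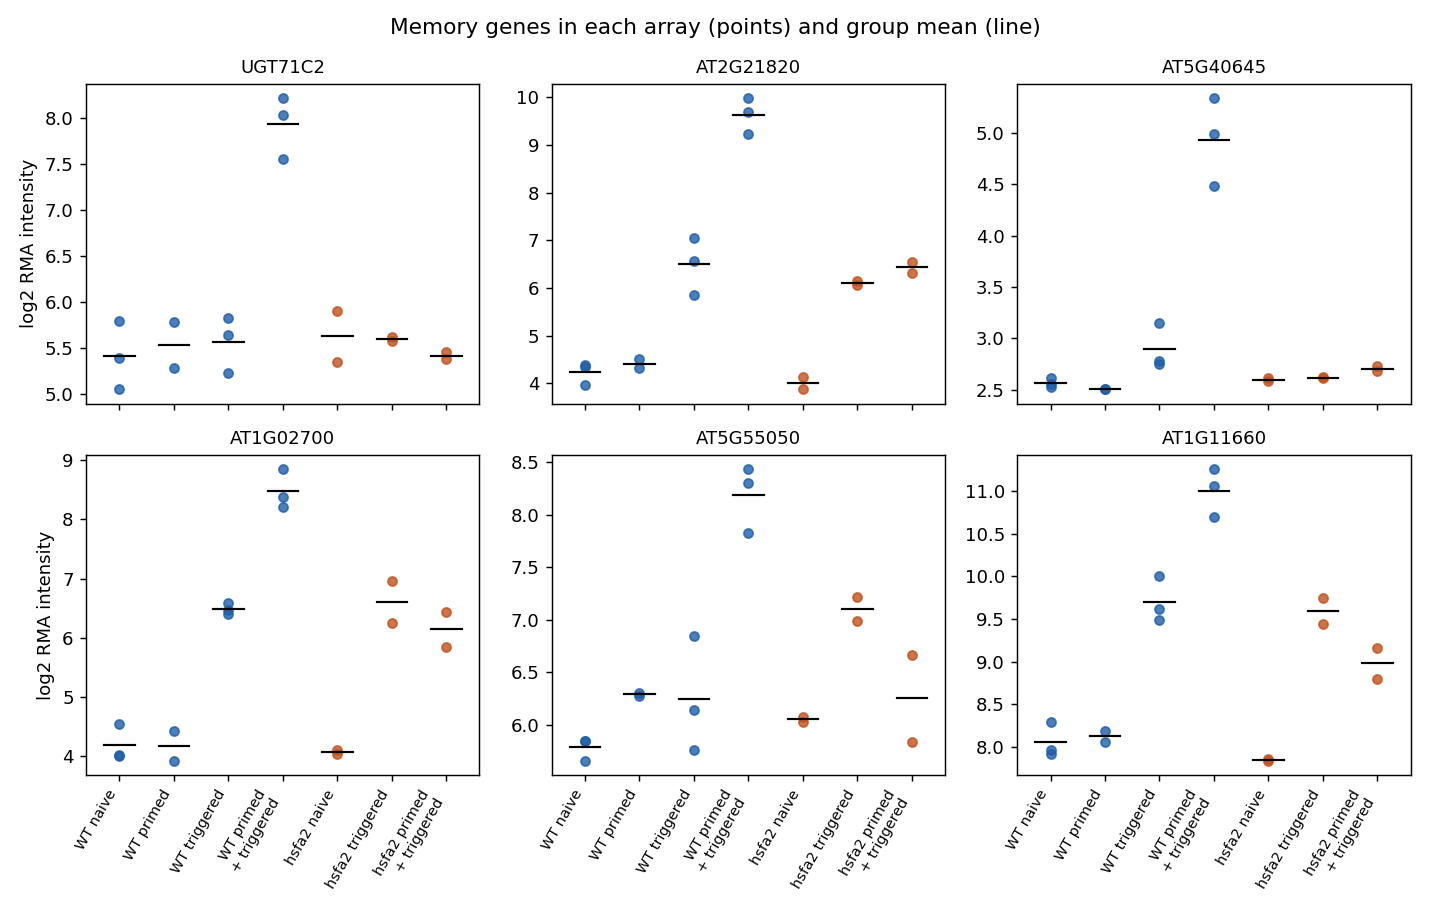
Log2 RMA intensity (vertical axes, separate scales) of UGT71C2, AT2G21820, AT5G40645, AT1G02700, AT5G55050 and AT1G11660 in each array (points; wild type blue, hsfa2 orange) and as the group mean (line), by group. AT2G21820 reached 9.63 in primed and triggered wild-type seedlings, against 6.49 after triggering alone and 6.44 in primed and triggered hsfa2 seedlings.

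The heat response without HSFA2 was read from triggered and naive hsfa2 seedlings. The heat shock genes rose there as well, although those near the top of the intensity range in both genotypes, such as ATHSP22.0 (13.12 in the wild type and 13.11 in hsfa2), could hide a difference. ATHSP22.0 rose by 8.99 (SE 0.57), Hop3 by 8.02 (SE 0.51), Fes1A by 6.72 (SE 0.25) and HSA32 by 5.54 (SE 0.54). The mitochondrial transcripts nad6, nad5, nad9 and nad4L rose by 7.00, 5.81, 5.36 and 5.04, ccb452 by 5.02 and STZ by 4.81 (SE 0.93). Of 10 small heat shock protein genes 8 rose, also adjusted over the list alone (median 7.92, camera adjusted p = 8.81e-16, and adjusted p = 0.0308 with an estimated correlation). Of 9 genes for HSP70, HSP90, HSP100 and partners 7 rose (median 3.68, adjusted p = 2.88e-17, and adjusted p = 0.00374 with an estimated correlation). The 3 memory genes of earlier work rose as well (median 7.55, adjusted p = 1.02e-08, and adjusted p = 0.0257 with an estimated correlation).

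The falls included BGLU33 (−2.91, SE 0.33), SBT4.12 (−2.66), sks15 (−2.60), NGA1 (−2.09), DRT100 (−2.03), ATSBT5.2 (−1.95), OCT5 (−1.87), AGL16 (−1.80), BRH1 (−1.77) and ZW9 (−1.76). All 3 root markers fell, PYK10 to −1.36 (SE 0.25), with a list median of −1.36 (camera adjusted p = 0.000209, and adjusted p = 0.0311 with an estimated correlation). Expansins and xyloglucan enzymes (2 of 11 lower over all probe sets and over the list alone, median −0.67, adjusted p = 0.00889) and photosynthesis genes (1 of 7 lower, 2 over the list alone, median −0.29, adjusted p = 0.00335) did not pass with an estimated correlation (adjusted p = 0.176 and 0.0873). The other 5 lists had camera adjusted p-values between 0.202 and 0.749.

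In hsfa2, limma called 1908 probe sets after triggering, 797 higher and 1111 lower, which became 1152 and 698 with each array centred on its median. Called in both genotypes were 704 of the probe sets higher after triggering, with 47.0 expected for independent lists, and 976 of those lower, with 106 expected, and 0 were called in opposite directions. The hsfa2 count was 870 and 828 without naive replicates 1 and 2 of hsfa2, and 975 and 1039 without triggered replicates 1 and 2. Array weights raised it to 5771, and a fit of only these 4 arrays raised it to 5084.

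Direct comparison of the genotypes found 1 large difference after heat. The unnamed probe set 266841_at, chosen after its values were seen, was at 12.46 ± 0.29 (SD, n = 3) in triggered wild-type seedlings and at 3.70 ± 0.02 (SD, n = 2) in triggered hsfa2 seedlings, a difference of −8.77 (SE 0.19, limma adjusted p = 1.81e-11). Its level in hsfa2 was near that of unheated seedlings and near background, so this difference is a lower limit. No such bound holds for a difference between responses, which also subtracts changes between levels near background. The annotation used here does not give its gene. It was therefore not determined here whether this probe set measures the disrupted gene itself or a gene that depends on it. This probe set was the only one called in the genotype difference of the heat response (−8.50, SE 0.26), where 269 reached an unadjusted p under 0.05 and the lists had camera adjusted p-values between 0.185 and 0.973. These 269 are far fewer than the share of 0.05 of all probe sets that would be reached without any difference. A single call therefore does not show that the heat responses of the genotypes were otherwise alike. That count of 1 was 4 without naive replicate 3 of the wild type or with the batch as a block, 2 with array weights, the dim filter or the variance trend, and 29 without hsfa2 triggered replicate 1. The second probe set that differed after triggering, that of AT5G20200, was higher in hsfa2 by 1.31 (SE 0.16, adjusted p = 0.0146). It was no longer called without any 1 of the 3 wild-type triggered arrays or without hsfa2 triggered replicate 2, and without hsfa2 triggered replicate 1 the comparison gave 31 calls, while 4 were called with the replicate numbers as a block, 5 with the batch as a block and 14 with array weights.

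Without heat, limma called 0 probe sets between the genotypes (smallest adjusted p = 0.0766, with 1317 at an unadjusted p under 0.05), and camera adjusted p-values of the lists lay between 0.155 and 0.934. The count was 4 with the spike-in batch as a block and 12 without the arrays of low bioB signal, settings chosen after seeing the data, 37 with array weights, 5 without naive replicate 2 of the wild type and 4 without its naive replicate 3. After triggering, 3 lists passed camera between the genotypes, each with an adjusted p = 0.0297 and an adjusted p = 0.413 with an estimated correlation, and 0 of their members were called by limma (1576 probe sets had an unadjusted p under 0.05). They were expansins and xyloglucan enzymes (median 0.20, 1 of 11 higher adjusted over the list alone, XTH18 at 1.34, SE 0.36), the cell cycle list (median 0.55, with AUR2 at 0.69, SE 0.26) and the abscisic acid and dehydration list (median −1.77, with COR15A at −2.38, SE 0.97). The other 8 lists had adjusted p-values between 0.240 and 0.983.

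Whether memory depends on HSFA2 was read from the same 69 probe sets in the mutant. Their median change with priming before triggering was 1.15 log2 units in the wild type and −0.15 in hsfa2, where 13 of the 69 (18.8%) were above 0. UGT71C2 was at 5.41 ± 0.05 in primed and triggered and at 5.60 ± 0.03 in triggered hsfa2 seedlings, AT2G21820 at 6.44 ± 0.16 and 6.10 ± 0.06, and AT5G40645 at 2.70 ± 0.03 and 2.62 ± 0.00 (SD, n = 2 each). For the single probe set that was lower in the wild type, AT5G40450, the change in hsfa2 was −0.02. In 100 simulations with equal effects in both genotypes, the median in hsfa2 of the probe sets called in the wild type lay between 1.05 and 1.33, and the share above 0 between 93.8% and 100%. With effects of 0.5 times the size, these ranges were 0.58 to 1.92 and 75% to 100%, but rest on the 0 to 10 probe sets (median 2) then called in the wild type. The simulated effects were scaled from the changes measured for the called probe sets, so the hsfa2 median was largely set in advance. The simulations therefore do not show how far selection in the wild type lowers the change in hsfa2. They also gave all groups the same spread and no pairing, unlike the arrays, so their counts of calls are no matched reference.

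The difference in memory between the genotypes was called by limma for 11 probe sets, all with a smaller change in hsfa2. The simulations, which were not matched to the arrays in spread or pairing, gave at most 2. The 11 probe sets called in the arrays were 249139_at (−3.05, SE 0.44), AT2G21820 (−2.80, SE 0.41), AT5G55050 (−2.79, SE 0.41), 256652_at (−2.74, SE 0.27), UGT71C2 (−2.56, SE 0.38), AT1G02700 (−2.46, SE 0.37), 246844_at (−2.18, SE 0.32), AT5G40645 (−1.96, SE 0.27), AT1G11660 (−1.91, SE 0.28), 253633_at (−1.52, SE 0.21) and 254360_at (−1.46, SE 0.21), with adjusted p-values between 0.00313 and 0.0362. Over the 69 probe sets the median of this difference was −1.35. No list passed camera (adjusted p between 0.205 and 0.997).

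In hsfa2 alone, limma called 0 probe sets between primed and triggered and triggered seedlings, with 1331 at an unadjusted p under 0.05 and a smallest adjusted p of 0.753. The simulations with equal effects, whose spread was not matched to the hsfa2 arrays, gave 27 to 49 calls. With effects of 0.5 times the size they gave 0 to 4, so the count alone does not separate a lost from a smaller response. Camera adjusted p-values of the lists lay between 0.158 and 0.957 there. The count of 0 was 29 without hsfa2 triggered replicate 1, all lower, 1 without hsfa2 triggered replicate 2, and 14 with array weights. The count of 11 was 2 without triggered replicate 1 or without primed and triggered replicate 1 or 3 of the wild type, 5 without triggered replicate 2 and 4 without triggered replicate 3. Without hsfa2 triggered replicate 2 or hsfa2 primed and triggered replicate 2 it was 1, without hsfa2 triggered replicate 1 it was 39, and in a fit of only these groups it was 0. It was 27 without the arrays of low bioB signal and 89 with array weights. With the replicate numbers as a block, UGT71C2 (adjusted p = 0.0632) and AT1G02700 (adjusted p = 0.0878) missed the threshold at the same changes. That block also joins hsfa2 to wild-type arrays by number, where the data gave little sign of pairing. The deviations correlated at −0.11 and −0.16 between the genotypes after triggering, and at 0.06 and 0.11 after both treatments.

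**Figure D3:**
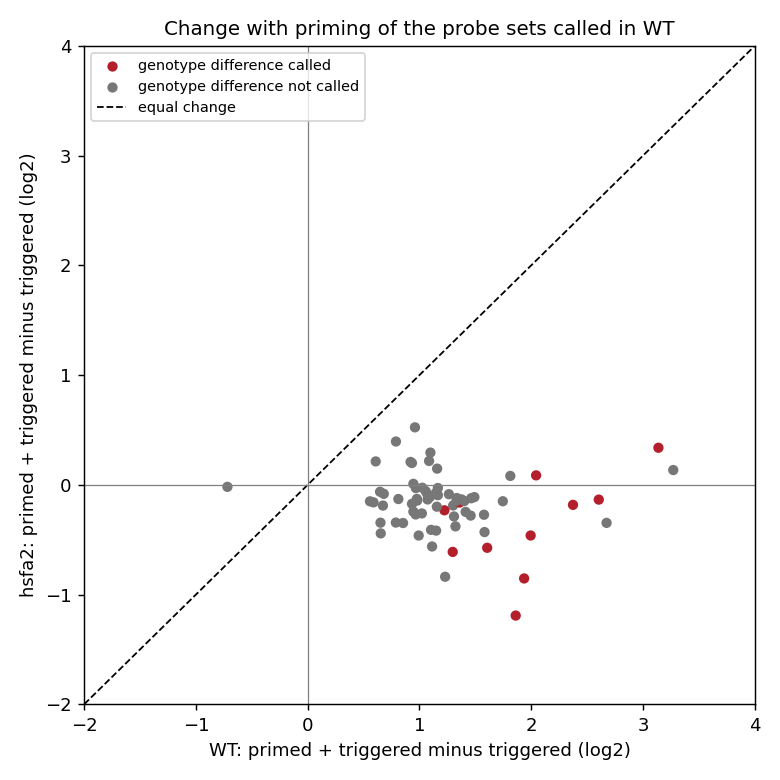
Log2 change from triggered to primed and triggered seedlings in the wild type (horizontal axis) and in hsfa2 (vertical axis) for the 70 probe sets called in the wild type (points; red where the genotype difference of the change was called, grey elsewhere; dashed line, equal change). Of the 69 probe sets to the right of 0, 13 lie above 0 for hsfa2.

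After priming and triggering, the genotypes themselves differed at 311 probe sets, 130 higher and 181 lower in hsfa2 (106 and 248 with each array centred on its median). Among the lower genes were UGT71C2 (−2.53, SE 0.27), the expansin-like gene EXLA1 (−1.95, SE 0.32), the glutathione transferase gene GSTU20 (−1.78, SE 0.34), CXE16 (−1.65) and TET2 (−1.65). Smaller differences were those of the acyl-carrier-protein thioesterase gene FaTA (−1.17), UBA1A (−1.16), the transcription factor gene bZIP44 (−1.15), SRC2 (−1.07) and LCR68 (−1.03). GSTU20 was at 8.54 ± 0.32 (SD, n = 2) in hsfa2 and at 10.32 ± 0.09 (SD, n = 3) in the wild type. The largest difference was again that of 266841_at (−8.97, SE 0.19), chosen after its values were seen. Higher in hsfa2 were JRG21 (1.25, SE 0.25), the chromatin remodeller gene ATRX (0.95), IAGLU (0.93), the F-box gene FBL17 (0.90), KICP-02 (0.88), the histone deacetylase gene HDA15 (0.87), KEU (0.80), SBT1.3 (0.74), ZAP1 (0.67) and CSA1 (0.65).

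No gene list passed camera in this comparison (adjusted p between 0.490 and 0.950), and the small heat shock protein list had a median of −0.25. The count of 311 was 140 without primed and triggered replicate 1 of the wild type, 498 without replicate 2 and 146 without replicate 3, and 72 or 33 without replicate 1 or 2 of hsfa2. It was 5 in a fit of only these 5 arrays, 1726 with array weights and 533 without the 3 arrays of low bioB signal.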

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

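Among the tests reported in this part, the comparison of the genotypes after triggering alone, the allowance for the spread between the primed arrays in the batch test, and the batch settings themselves were chosen after the results had been seen.

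Differences between responses were tested as interactions with limma. The response to later heat differed between primed and unprimed wild-type seedlings for 4 probe sets: AT2G21820 at 2.96, 256652_at at 2.66, AT5G40645 at 2.104 and AT1G68620 at 1.46. All primed arrays lie in the batch of low bioB signal, and this count fell to 1 with that batch as a block. None was called without the naive arrays of high bioB or with only the groups compared. The heat response differed between the genotypes for 1 probe set, 266841_at at −8.50, whose log2 intensity lay between 12.19 and 12.79 in the 6 heated wild-type arrays and between 3.18 and 3.71 in the 6 hsfa2 arrays. It is not listed in the annotation used here, so it was not determined here whether it measures the disrupted gene itself. As its low values are near background, the size of this difference between responses is uncertain in both directions. The memory response differed between the genotypes for 11 probe sets: 249139_at at −3.05, AT2G21820 at −2.80, AT5G55050 at −2.79, 256652_at at −2.74, UGT71C2 at −2.56, AT1G02700 at −2.46, 246844_at at −2.18, AT5G40645 at −1.96, AT1G11660 at −1.91, 253633_at at −1.52 and 254360_at at −1.46. With the replicate numbers as a block, UGT71C2 (adjusted p = 0.0632) and AT1G02700 (adjusted p = 0.0878) of these were not called. That block also joins arrays of the 2 genotypes by number, where the data gave little sign of pairing. Outside the measured transcripts, the control probe sets set 3 arrays apart (wild-type naive replicate 3 and both primed replicates), with bioB −3.23 log2 units from the other 14 and the poly-A spikes 2.95 above their mean. By the poly-A spikes alone, wild-type naive replicate 2, at 8.83, lay near these 3 arrays.

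The probe sets that rose with priming in the wild type did not do so in hsfa2, and selection on the wild-type arrays alone would give such a contrast. When as many probe sets were chosen anew on 2 of the 3 wild-type replicate numbers, the left-out number still gave medians of 1.21, 0.99 and 1.01, of which the lowest (0.985) exceeds the bound of 0.5 set before the test, while hsfa2 lay between −0.15 and −0.13. A technical shift of all hsfa2 arrays would lower these probe sets in the mutant after triggering alone too, where the median difference from the wild type was −0.0930, against −1.38 after priming and triggering. Both differences subtract the wild-type arrays on which the probe sets were picked, so selection alone would raise the first and lower the second. Between naive seedlings, whose levels took no part in that choice, the median difference was −0.02. A loss of the memory response without HSFA2 remains a candidate explanation, as a hypothesis found and tested on the same arrays, and a difference in growth or in the handling of the primed and triggered mutant seedlings, which the arrays do not measure, stays open. The other splits of the 6 wild-type arrays that part the same pairs gave at most 0 calls against the real 70, and at most 0 heat-induced probe sets higher after priming against the real 47, but with 1 of 4 splits as large, the real one, the splits are too few to judge chance.

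Small heat shock protein transcripts had a list median of 1.4003 above naive in primed seedlings, and the primed arrays differed. The lower of both array medians was 0.241, below the bound of 0.5, so the pattern could rest on primed replicate 2 alone (2.37), whatever its source. A hybridization batch was tested within the arrays of low bioB signal, where the median stayed at 0.936. This lies above 0.5 times the value over all arrays, the bound set beforehand, but by less than the SD of 1.32 between the primed arrays, and with a single naive array in the batch the explanation stays open. By the bound alone the batch would have been ruled out; the allowance for the spread was added after this value had been seen. Residual heat shock transcripts 3 d after priming, which the design would allow, cannot be told apart from a single deviating sample.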

How the results depend on the processing

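The settings that use the spike-in controls and the paired fit of 6 arrays were chosen after seeing the data, while all others were fixed beforehand.

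Directions of named genes mostly held: of 199 values recomputed under the alternatives, 0 reversed as calls. Of the results, 2882 kept their side of the threshold, 365 lost it, 11 gained it and 8 changed sign without passing in either fit. Counts of calls moved more, and the cause was not tested where the setting does not itself remove arrays or probe sets. After priming alone the count of 1 became 0 with the dim filter, 2 with a variance trend, 0 with the spike-in batch as a block, 0 without the naive arrays of high bioB, 0 with only the groups compared, and 0 to 542 with 1 array left out. After triggering, 3502 became 1832 with only the groups compared and 1432 with a 2-fold minimum. For memory, 70 became 4 with only the groups compared, 46 with a 2-fold minimum and 19 to 88 with 1 array left out, and the 47 heat-induced ones 15 to 50. The 4 interaction calls of the wild type became 1 with the batch block, 0 without the naive arrays of high bioB, 0 with only the groups compared and 1 to 29 with 1 array left out. The mean heat response of 5199 became 1642 with a 2-fold minimum. The overlap of primed and memory calls was 0 to 3 with 1 array left out.

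Between the genotypes without heat, 0 became 37 with array weights, 4 with the batch block, 12 with only the arrays of high bioB and 0 to 5 with 1 array left out. After triggering, 2 became 1 with centred arrays, 14 with weights, 4 with the replicate block, 5 with the batch block, 5 with only the arrays of high bioB, 1 with only the groups compared and 1 to 31 with 1 array left out. After both treatments, 311 became 1726 with weights, 533 with only the arrays of high bioB, 5 with only the groups compared, 146 with a 2-fold minimum and 33 to 498 with 1 array left out. In hsfa2 the heat count of 1908 became 5771 with weights, 5084 with only the groups compared, 1168 with a 2-fold minimum and 828 to 1039 with 1 array left out, and the memory count of 0 became 14 with weights and 0 to 29 with 1 array left out. For the genotype difference of the heat response, 1 became 2 with the dim filter, 2 with the variance trend, 2 with weights, 4 with the batch block, 4 with only the arrays of high bioB and 1 to 29 with 1 array left out. For that of the memory, 11 became 89 with weights, 27 with only the arrays of high bioB, 0 with only the groups compared and 1 to 39 with 1 array left out. Arrays left alone in a group were assumed to vary like the others. Replicate arrays of hsfa2 differed less (SD of the difference between 0.19 and 0.31) than those of the wild type (0.37 to 0.64), and a shared spread then makes hsfa2 tests stricter and wild-type tests more lenient than the group's own spread would.

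Of 132 list tests, 29 passed at the preset correlation and 9 with an estimated one. With the replicate block, memory calls in the wild type were 61 and heat calls 3821, the pairing of 6 arrays alone gave 142, and among the named genes the block changed 3 calls (UGT71C2 and AT1G02700 in the genotype difference of the memory, and RCA at −0.25 in the mean heat response, adjusted p = 0.0595). Triggered and primed and triggered arrays of the wild type each correlated best with their own number. Naive arrays correlated with triggered arrays of the same number at −0.16, 0.57 and 0.18, a hint that only some numbers were shared. Array number, and signal near background for dim probe sets, limit what can be called.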

Other observations

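The organelle lists, both tests on mitochondrial transcripts and the restriction of the splits to those that keep pairs together in this part were chosen after the results had been seen.

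Transcripts of the mitochondrial genome rose after heat. Of 11 measured genes 10 rose in the triggered wild type, with a median of 4.05 log2 units (camera adjusted p = 1.00e-14, and adjusted p = 0.00878 with an estimated correlation), and 8 rose in hsfa2, with a median of 4.04 (adjusted p = 0.00740 with an estimated correlation). Beyond the genes named in the report, cox1 rose by 4.05, nad1 by 3.44, matR by 2.65, nad7 by 1.33 and nad2 by 0.52 in the wild type, while nad4 was at 0.57 (SE 0.39) and did not pass. Over arrays the list median was 4.64 ± 0.63 in naive, 4.51 ± 0.05 in primed, 9.43 ± 0.64 in triggered and 9.38 ± 0.80 in primed and triggered wild-type seedlings (SD), and 4.36 ± 0.00, 9.09 ± 0.01 and 8.91 ± 0.17 in naive, triggered, and primed and triggered hsfa2 seedlings. Priming did not add to it: the median change from triggered to primed and triggered seedlings was −0.09 in the wild type, with 0 of 11 genes called by limma (1098 of all probe sets at an unadjusted p under 0.05).

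Plastid-encoded transcripts did not share this rise. Of 69 genes 6 fell in the triggered wild type, with a median of −0.83 (adjusted p = 0.336 with an estimated correlation), among them rps18 at −2.37, and 0 of 69 were called in hsfa2 by limma (4784 of all probe sets at an unadjusted p under 0.05). The wild-type arrays differed widely, with list medians of 10.73, 9.44 and 10.37 in the naive replicates 1, 2 and 3, of 7.51, 9.25 and 10.61 in the triggered replicates 1, 2 and 3 and of 7.88, 9.12 and 10.89 in the primed and triggered ones, against 9.16 and 9.33 in the triggered hsfa2 arrays. The lower level thus came mainly from replicate 1, while replicate 3 was not lower after triggering, and no fall of the group is claimed. Replicate 1 of both heated groups also had larger differences between 3′ and 5′ GAPDH signals (1.57 and 1.69) than replicates 2 and 3 (0.52 to 0.94), so RNA quality was not told apart from heat there.

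For the mitochondrial rise, RNA integrity was tested on the unheated wild-type arrays with the largest difference between 3′ and 5′ GAPDH signals, which lay 0.0198 above the other unheated arrays, far below 0.5 times the rise. They are the 3 arrays of low bioB signal, so integrity was not told apart from that batch, and the other unheated wild-type arrays differed (5.20 and 3.95). The comparison thus speaks only against an effect as large as the rise, if the batch did not offset it. More RNA of every organelle in the labelled material would raise plastid transcripts too, and these were at −0.244 in hsfa2 after triggering. The rise may therefore reflect a change specific to mitochondrial transcripts, as a hypothesis. A change in their polyadenylation, on which labelling from the 3′ end depends, and transcription of the copy of mitochondrial DNA in the nuclear genome were not tested and remain open.

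Regrouping of the wild-type arrays left chance open for the heat counts. As triggered and primed and triggered arrays of a number are paired, 10 splits of the 9 arrays keep the pairs together. Of these 1, the real one, gave as many calls as the mean heat response (5199), and the highest other gave 1170 (naive, triggered, and primed and triggered replicate 2 against the rest). For triggered against naive, 1 of 10 splits gave as many as 3502 and the highest other 0. In both cases 10 splits are too few for a share under 0.05.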
